A study of Mus musculus with 8 samples.

How the data were processed

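RNA was extracted from dissected brown adipose tissue and, per the labels' protocols, checked for integrity on a Bioanalyzer and made into libraries with a NEBNext Ultra RNA kit. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 from the Subread package, and the mm10 genome build, without saying whether strand was used in counting. The labels carry the same batch value for all 8 samples. The spelling of the inducing agent in the labels is unclear, so only the induction is given here. The cell type label reads adipocytes, but the tissue was taken whole, and values are read as those of tissue.

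The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled for sequencing depth) for 54532 genes in 8 libraries, with gene identifiers, symbols, positions, biotypes and lengths. Multiplied by gene length, the deposited FPKM values of each library came out as whole multiples of a single read in 100% of cases (tolerance 0.001), so whole reads per gene were back-calculated. The denominators of the deposited FPKM were not the library totals: they equalled median-of-ratios size factors times the geometric mean of the totals, and ranged from 0.790 (WT 3) to 1.13 (OGTBKO 3) times the library's own total. The values are therefore already scaled between libraries, and a fold change is relative to the typical gene. Reads in genes numbered 13423798, 14323963, 13393962 and 15293657 in WT 1 to WT 4 and 15897920, 15135731, 15866275 and 14409348 in OGTBKO 1 to OGTBKO 4. At this depth 1 read in a gene of 1 kb was worth between 0.0556 and 0.0945 FPKM. No value columns were left out. Of the gene identifiers 99.9% were found in GENCODE M21, and 98.3% had the same coordinates there, which places the table on mm10.

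Libraries of a group were compared in pairs by a chi-square over genes of the back-calculated reads, which gave between 16.0 and 99.6 per degree of freedom, so no 2 libraries of a group were the same material sequenced again; pairs across the groups were not compared in this way. Values were analysed as log2(FPKM + 0.5) without further scaling, for the 13171 genes (11338 of them protein-coding) with a mean of at least 0.5 FPKM over the 8 libraries. The fold changes are on that scale, which understates the change of genes with low values. OGTBKO was compared with WT by limma 3.58.1 in R 4.3.3 (moderated test, eBayes with a mean-variance trend, two-sided) without covariates, with Benjamini-Hochberg adjustment over all genes kept. Every adjusted p of a single gene comes from that limma fit, or from the same test under the changed setting named beside it. Errors beside FPKM means are SDs over 4 libraries and errors beside log2 changes are SEs of the fit. Where 1 value per library was compared, an exact two-sided permutation test over the 70 assignments was used, whose smallest p is 0.0286.

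For gene lists, 38 lists of genes were written down before the data were examined, covering O-GlcNAc cycling, vascular factors, cell types that dissected fat can hold, fat metabolism, stress and immune responses, and RNA quality. The 33 lists with at least 5 kept members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with camera at an estimated correlation and with fry, directional and mixed, beside it. Counts of members are also given adjusted over the list alone. No cell shares were estimated. Older symbols in the table were matched to current ones. Where a symbol belonged to several gene models, the model with the higher mean was taken.

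The genes named were set by a rule fixed before the data were examined: Ogt and Oga; the 12 largest rises and 12 largest falls among genes with adjusted p under 0.05, groups that did not overlap, a mean of at least 1 FPKM, protein-coding, and a symbol without the marks of gene models and clones that the rule listed (Gm with digits, an ending in Rik, or a start with AC, AI, BC or ENSMUSG); up to 4 members with the smallest p of each list described; and Vegfa, Pecam1, Cdh5, Kdr, Ucp1, Adipoq, Ppargc1a and Lep in any case. CAAA01147332.1 is a gene model too, but bears none of the marks listed, so it was kept. Members of a list that was called were also open to naming.

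The steps were tested on simulated reads drawn with the means and within-group spread of the real libraries. Of genes changed 1.5-fold, 15.4% were recovered (10 of 65), of those changed 2-fold 54.5% (36 of 66) and of those changed 4-fold 81.8% (54 of 66), with 8 false calls among 12922 unchanged genes (7.41% of the calls). Far fewer genes were changed in the simulation than were called in the real data (2050). Fewer changed genes make the Benjamini-Hochberg adjustment stricter, so the recovery may be understated. Each gene was drawn independently, so the share of false calls does not cover trends that many genes share within a library. A simulated GC slope of 0.03 log2 per percentage point over 13213 genes gave fold changes with a slope of 0.0246; limma called 0 genes with that trend and 0 after its removal, so the simulation does not show how the removal acts on calls. Alternatives planned before the data were examined covered the pseudocount, the filter, other scalings, the variance model, array weights, protein-coding genes alone, limma voom on the back-calculated reads, the replicate number as a block, and each library left out in turn. Added afterwards were the library total as denominator, removal of each library's trend on GC content and length together or singly (natural splines with 4 degrees of freedom; GC content of each gene's longest GENCODE M21 transcript, known for 99.9% of genes kept), leaving out both libraries numbered 1, and leaving out WT 3 together with the trend removal. The closing section gives their effects. Plots and tables were made with Python 3.11.15 (pandas 2.3.3, matplotlib 3.10.9).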

Results

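Brown adipose tissue, the fat depot that burns lipid to produce heat, was profiled by RNA sequencing in 8 mouse samples. They fell into 2 groups of 4: wild-type tissue (WT) and tissue with a brown adipocyte-specific knockout of Ogt (OGTBKO). OGT is the enzyme that attaches O-linked N-acetylglucosamine (O-GlcNAc) to serine and threonine residues of intracellular proteins, and OGA removes it. The animals were housed at 23 °C on standard chow and induced after 8 weeks, and the tissue was taken 2 months later, cleared of the white fat around it. The title of the series names vascularization of brown fat by signals from adipocytes, so the comparison asks which genes differ when adipocytes lack Ogt, secreted vascular factors and vascular cell markers among them. Between 13393962 and 15897920 reads per library fell in genes. Mitochondrial genes took between 27.2% (WT 4) and 39.4% (WT 3) of them in WT libraries. In OGTBKO libraries they took between 25.2% (OGTBKO 3) and 30.2% (OGTBKO 2). The labels number the samples without saying outright that each came from a separate animal, so the p-values measure the spread between these samples.

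The targeted gene was lower in every OGTBKO library. Ogt (ENSMUSG00000034160, chromosome X, 101640060 to 101684351, plus strand, mm10) measured 33.1, 24.7, 23.9 and 22.5 FPKM in the 4 WT libraries and 10.7, 14.5, 12.8 and 11.8 FPKM in the 4 OGTBKO libraries. The means were 26.0 ± 4.80 and 12.4 ± 1.65 FPKM (SD, n = 4 each), a log2 change of -1.03 ± 0.14 (SE; limma adjusted p = 0.00511). The groups did not overlap, and the exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 allows. These values cover the whole tissue, in which cells other than brown adipocytes keep the gene, and the deleted exons are not given in the sources used here. Oga, listed under its older symbol Mgea5, fell with it, from 13.3 ± 2.64 to 7.24 ± 1.21 FPKM (log2 -0.83 ± 0.17, adjusted p = 0.0165). The Oga call ended in 1 of the fits with a single library left out and in 1 other alternative. Of the 13 measured genes of O-GlcNAc cycling and hexosamine synthesis, 2 were lower (Ogt and Oga), 0 were higher and 11 did not pass the test. Adjusted over the list alone, 2 were lower and 1 was higher. The next smallest p values belonged to Amdhd2 (log2 0.38, adjusted p = 0.0533) and Nagk (log2 0.30, adjusted p = 0.0943), which salvage amino sugars.

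**Figure D1:**
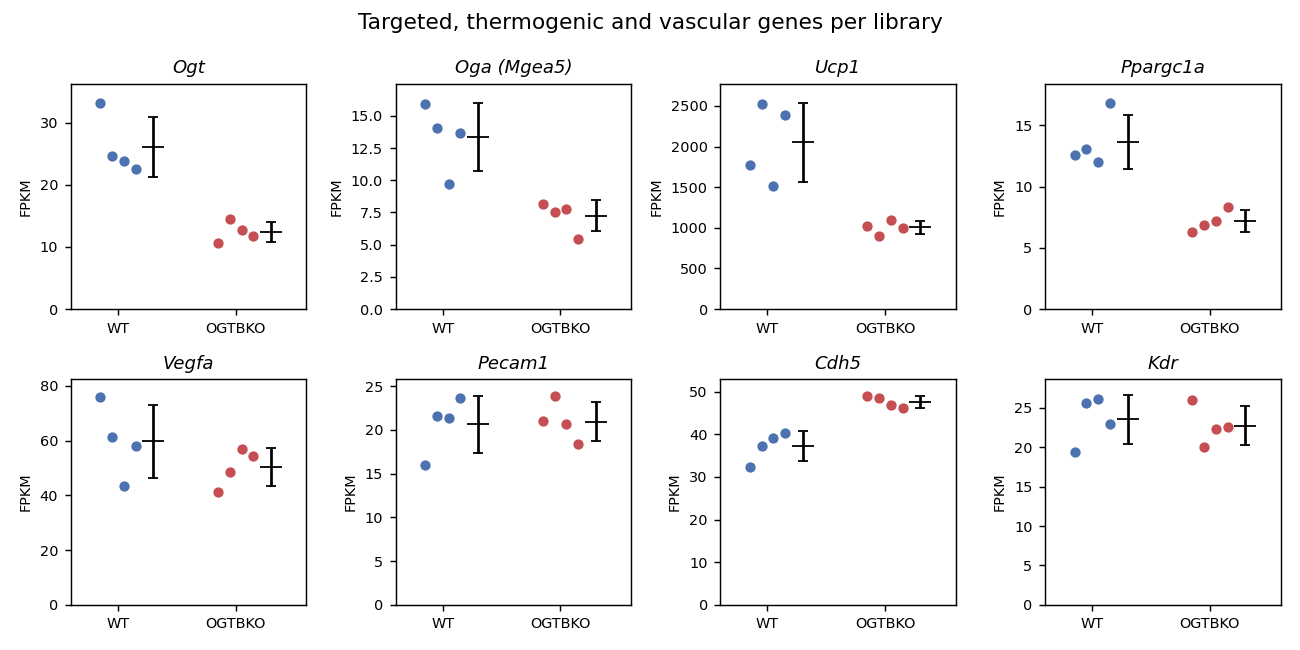
FPKM of 8 genes in each library (points), with the group mean and SD (bars, n = 4 each), on axes that start at 0. Ogt, Oga, Ucp1 and Ppargc1a were lower in all 4 OGTBKO libraries than in any WT library, Cdh5 was higher, and Vegfa, Pecam1 and Kdr overlapped between the groups.

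Across the transcriptome, 2050 of 13171 genes differed between the groups (limma, adjusted p under 0.05), 1068 higher and 982 lower in OGTBKO tissue, and 333 of them by at least 2-fold. Among protein-coding genes open to naming whose groups did not overlap, with a mean of at least 1 FPKM, the largest rise on the log2(FPKM + 0.5) scale belonged to Bmp8b, a growth factor that brown fat secretes and that enhances its response to adrenergic stimulation, from 0.372 ± 0.0581 to 7.37 ± 2.12 FPKM (log2 3.14 ± 0.19, adjusted p = 0.000227). Wwc1, a scaffold of the Hippo pathway, was listed at 0 in 3 WT libraries and at 0.0282 FPKM in WT 2, against 2.05 to 3.35 FPKM in OGTBKO libraries (log2 2.61 on the scale with the pseudocount). Cend1, linked to cell cycle exit in neurons, rose by a log2 of 2.57, the transferrin receptor Tfrc by 2.41, leptin (Lep) by 2.26, Nt5dc2 by 2.23, and the macrophage elastase Mmp12 by 2.22. Subunits of the proton pump that acidifies lysosomes rose as well, Atp6v0e2 by a log2 of 2.21 and Atp6v0d2 by 1.96, as did the oxidative stress gene Osgin1 by 2.15, the transcription factor Dmrt2 by 1.87 and CAAA01147332.1, a gene model on an unplaced scaffold, by 1.96. Under the same limits, no overlap between the groups included, the largest falls on that scale were those of Itih4, an inter-alpha-trypsin inhibitor chain, with a log2 of -2.39, the chemokine Ccl8 with -2.02, and the heat shock chaperone Hsph1 with -1.70, from 13.4 ± 2.88 to 3.77 ± 0.805 FPKM. Among the falls were also the protease inhibitors Serpina3n (log2 -1.60) and Serpina3k (log2 -1.53), members of a gene family so alike that reads can be shared among them. The bicarbonate cotransporter Slc4a4 (log2 -1.58), the interferon-induced Rtp4 (log2 -1.57), the glutamate transporter Slc1a3 (log2 -1.42) and betacellulin (Btc, log2 -1.42), a ligand of the epidermal growth factor receptor, were also lower. The nuclear receptor Nr4a3 (log2 -1.40), mitochondrially encoded mt-Co3 (log2 -1.35) and syndecan 4 (Sdc4, log2 -1.34) completed the 12 falls named. The calls of Ccl8, Serpina3n, Serpina3k, Slc4a4, Nr4a3, mt-Co3 and Sdc4 ended in at least 1 alternative tried, as did that of Lep. In WT 4 Sdc4 measured 64.5 FPKM, against 18.2 to 24.2 FPKM in the other WT libraries. The groups did not overlap in 22.5% of the genes tested, where chance gives 2.86%.

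The direction of change followed the base composition of the transcripts and, over all genes, their length. With the genes tested divided into 4 equal bins by GC content, 84 were higher and 581 lower in the lowest bin, and 456 were higher and 65 lower in the highest. In 4 equal bins by length, 422 were higher and 132 lower among the shortest genes, against 95 and 426 among the longest. The slope on GC content of each library's log2 level, taken relative to the mean of the 8 libraries so that the groups mirror each other, was lower in all 4 WT libraries (-0.0115 ± 0.00290 per percentage point, SD, n = 4) than in any of the 4 OGTBKO libraries (0.0115 ± 0.00809; exact two-sided permutation p = 0.0286, the smallest possible). The slopes on length, taken in the same way, overlapped between the groups (0.0183 ± 0.0391 in WT and -0.0183 ± 0.0162 in OGTBKO libraries per doubling; exact permutation p = 0.143). With the GC and length trend of each library removed, a setting chosen after the data were seen, 1051 of the 2050 genes were still called, of 1383 in all. With the library total as the FPKM denominator, also chosen afterwards, 980 genes were higher and 249 lower. The count was 3516 with array weights, 1229 with no filter on low values, 784 without WT 2, 1195 without WT 4, 1175 without OGTBKO 2, 692 without OGTBKO 3 and 945 without OGTBKO 4. Apart from Ogt, 96 of the genes that the naming rule selected were called, and 52 of these lost the call when at least 1 of the 8 libraries was left out. The call held in every alternative tried for 34 of them, Bmp8b, Tfrc, Hsph1, Tgfb1, Ppargc1a, Cox7a1, Nos3, Ifi27 and Ighm included. By contrast, the calls of Kdm3a, Bgn and Ehhadh each ended in 7 of the fits with a single library left out. Those of Idh2, Mdh2, Cd36 and Cyr61 each ended in 6 of these fits.

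**Figure D2:**
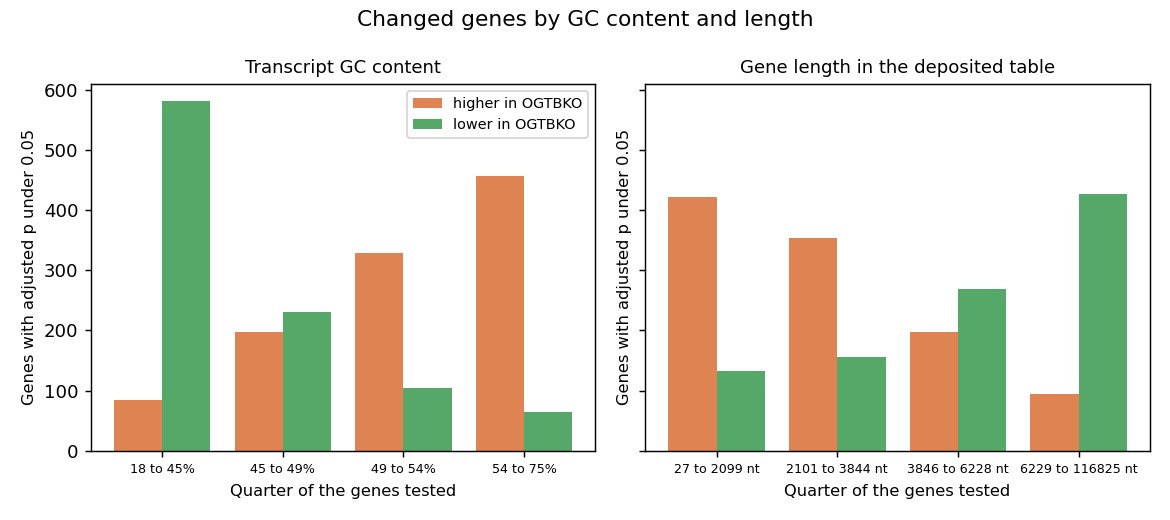
Number of genes higher (orange) and lower (green) in OGTBKO tissue (adjusted p under 0.05) in 4 equal bins of the tested genes, by transcript GC content in percent (left) and by gene length in nucleotides (right). Genes lower in OGTBKO numbered 581 in the bin of lowest GC content and 65 in the highest.

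Secreted vascular factors changed in both directions. Of all genes tested 15.6% were called, the share against which the counts of this and the other lists are to be read. Of the 22 measured pro-angiogenic factors, 3 were higher, 1 was lower and 18 did not pass the test, with the same counts adjusted over the list alone. Tgfb1, a growth factor with wide effects on vessels and matrix, rose from 2.59 ± 0.0686 to 5.80 ± 0.916 FPKM (log2 1.02 ± 0.11, adjusted p = 0.00236), Lep from 8.02 ± 4.68 to 34.2 ± 8.57 FPKM (adjusted p = 0.0186) and Cyr61, a matrix protein that binds integrins, from 4.35 ± 1.52 to 11.6 ± 5.15 FPKM (adjusted p = 0.0390). Pdgfc, a platelet-derived growth factor, fell from 2.02 ± 0.115 to 1.17 ± 0.270 FPKM (log2 -0.61, adjusted p = 0.0215). Vegfa, the main growth factor of endothelial cells, measured 59.7 ± 13.3 FPKM in WT and 50.2 ± 6.93 FPKM in OGTBKO tissue (log2 -0.23, 95% interval -0.62 to 0.16, adjusted p = 0.396), a difference within the spread between libraries. The list's median log2 change was -0.16 and its mean 0.06, of opposite sign, and it was not called (camera adjusted p = 0.737). The median went to -0.02 without OGTBKO 4 and to -0.07 without WT 2. Among 16 measured anti-angiogenic factors, 2 were higher and 0 lower, also when adjusted over the list alone: vasohibin 1 (Vash1), from 0.646 ± 0.152 to 1.51 ± 0.260 FPKM (adjusted p = 0.0121), and the Wnt antagonist Sfrp1, from 0.740 ± 0.0892 to 1.43 ± 0.227 FPKM (adjusted p = 0.0187). Serpinf1 (log2 0.73, adjusted p = 0.0682) and Col18a1 (log2 0.43, adjusted p = 0.102) did not pass. Once the GC and length trend was removed, Cyr61 (adjusted p = 0.0833) and Vash1 (adjusted p = 0.0737) were no longer called.

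Endothelial markers did not move as a group. Of 30 measured, 2 were higher, 2 lower and 26 not past the test, with the same counts adjusted over the list alone and a median log2 change of -0.01 (camera adjusted p = 0.939). That median was above 0 with the library total as denominator (0.11, camera adjusted p = 0.774), and with the GC and length trend removed 1 marker was higher and 3 lower. Pecam1 measured 20.6 ± 3.28 and 21.0 ± 2.25 FPKM in WT and OGTBKO tissue (log2 0.03, 95% interval -0.28 to 0.34), and Kdr, the main receptor of VEGF-A, 23.6 ± 3.09 and 22.7 ± 2.45 FPKM (log2 -0.05, 95% interval -0.33 to 0.23; log2 0.07 with the library total as denominator). The endothelial cadherin gene Cdh5 was higher, at 47.7 ± 1.39 against 37.3 ± 3.55 FPKM (log2 0.35 ± 0.10, adjusted p = 0.0413), a call that ended once the GC and length trend was removed (adjusted p = 0.0826). The Cdh5 call also ended in 7 of the fits with a single library left out. Endothelial nitric oxide synthase (Nos3) rose by a log2 of 0.78 ± 0.14 (adjusted p = 0.0115), whereas the sphingosine-1-phosphate receptor S1pr1 fell by 0.69 on the log2 scale (adjusted p = 0.0103) and the endothelial adhesion receptor Adgrl4 fell by 0.58 (adjusted p = 0.0122). These 3 remained called after the removal. Of 15 pericyte and smooth muscle markers, 2 were higher and 0 lower, over all genes and adjusted over the list alone: Kcnj8, a potassium channel of pericytes (log2 0.61, adjusted p = 0.0144), and Ndufa4l2 (log2 0.81, adjusted p = 0.0192), neither of them called after the removal. Of 3 measured lymphatic endothelial markers 0 passed in limma, with Lyve1 at a log2 of -0.74 (adjusted p = 0.272), Flt4 at 0.22 (adjusted p = 0.324) and Pdpn at -0.19 (adjusted p = 0.769). Hypoxia and HIF target genes included 5 that were lower and 0 higher of 20 measured (5 and 1 adjusted over the list alone; camera adjusted p = 0.381). P4ha1, a collagen prolyl hydroxylase, fell from 10.2 ± 1.75 to 4.85 ± 0.907 FPKM, the mitophagy receptor Bnip3 fell by 1.24 on the log2 scale, the glycolytic regulator Pfkfb3 fell by 0.70 and the histone demethylase Kdm3a fell by 0.39 (adjusted p = 0.0442, and 0.177 after the removal of the trend).

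Thermogenic genes were divided. Of 30 measured genes of brown fat identity, 6 were lower, 3 higher and 21 not past the test (8 and 4 adjusted over the list alone). Ucp1, the uncoupling protein that releases heat, fell from 2051 ± 485 to 1006 ± 79.3 FPKM (95% interval of the log2 change -1.42 to -0.58, adjusted p = 0.0113). The Ucp1 call ended in 2 alternatives and in 0 of the fits with a single library left out. The coactivator Ppargc1a fell from 13.6 ± 2.19 to 7.17 ± 0.878 FPKM (adjusted p = 0.00628), and the lipid droplet protein Plin5 fell by 0.71 on the log2 scale. Bmp8b rose, and so did the cytochrome oxidase subunit Cox7a1, from 93.2 ± 16.1 to 205 ± 13.5 FPKM (adjusted p = 0.00317). The list's median log2 change was -0.32, and its test did not pass (camera adjusted p = 0.110). The list was called lower without both libraries numbered 1 (adjusted p = 0.0405) and without WT 3 with the GC and length trend removed (adjusted p = 0.0245). Over all 27 alternatives its median stayed below 0. Markers of white adipose tissue had a median log2 change of 0.59 (2 of 9 higher, 0 lower; 4 and 0 adjusted over the list alone; camera adjusted p = 0.110). The list was called with no filter on low values (adjusted p = 0.0251) and without OGTBKO 4 (adjusted p = 0.0205). Lep and gamma-synuclein (Sncg, log2 1.40, adjusted p = 0.0275, and 0.0603 with the GC and length trend removed) passed, and Nnat (log2 1.29, adjusted p = 0.0551) and resistin (Retn, log2 1.09, adjusted p = 0.0634) did not.

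General adipocyte genes held their level as a list (median log2 0.08, camera adjusted p = 0.822), with 4 of 24 higher and 3 lower (6 and 3 adjusted over the list alone). With the GC and length trend removed 2 were higher and 3 lower, with a median of -0.12. Adiponectin (Adipoq) measured 365 ± 35.7 and 440 ± 63.7 FPKM (log2 0.26, 95% interval -0.05 to 0.58, adjusted p = 0.225). Hormone-sensitive lipase (Lipe) rose by a log2 of 0.60, and Pck1, the glycerol-forming carboxykinase, fell from 841 ± 186 to 395 ± 108 FPKM (adjusted p = 0.0169). The fatty acid transporter Cd36 fell by 0.48 (adjusted p = 0.0275, and 0.147 with the GC and length trend removed). In de novo lipogenesis 2 of 18 genes were higher and 0 lower (3 and 1 adjusted over the list alone): Thrsp rose by a log2 of 1.02 ± 0.26 (adjusted p = 0.0316) and the regulator Srebf1 rose by 0.61 (adjusted p = 0.0263). Neither was called after the removal. Fatty acid oxidation had 1 gene higher and 1 lower of 22 (1 and 0 adjusted over the list alone), the electron transfer flavoprotein subunit Etfb (log2 1.19, adjusted p = 0.00613) and the peroxisomal enzyme Ehhadh (log2 -1.03, adjusted p = 0.0489, and 0.0507 after the removal). Nuclear-encoded oxidative phosphorylation had 4 of 47 higher and 0 lower, also when adjusted over the list alone: Ndufa9 (log2 0.60), Cox5b (log2 0.80), Atp5o (log2 0.78) and Cox6b1 (log2 0.64). With the GC and length trend removed, 3 members were higher and 6 lower, Ndufa9 and Cox5b among those still higher, and the list's median log2 change went from 0.06 to -0.06. Of 19 tricarboxylic acid cycle genes, 2 rose, also when adjusted over the list alone, Idh2 (log2 0.45) and Mdh2 (log2 0.42), and neither was called after the removal, where 0 were higher and 1 lower. Glycolysis had 1 of 17 higher, hexokinase 1 (Hk1, log2 0.98, adjusted p = 0.0137), and 1 lower, Pfkfb3, also when adjusted over the list alone. None of these lists was called.

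Transcripts of the mitochondrial genome were lower as a list (camera adjusted p = 0.0237; median log2 -0.68; adjusted p = 0.936 with an estimated correlation). Of its 13 members 2 were lower and 0 higher, and 5 were lower adjusted over the list alone. mt-Co3, a subunit of cytochrome oxidase, fell from 3221 ± 802 to 1291 ± 468 FPKM (adjusted p = 0.0191) and mt-Atp8, of the ATP synthase, from 21.5 ± 7.28 to 8.27 ± 3.84 FPKM (adjusted p = 0.0285, and 0.154 with the GC and length trend removed). mt-Atp6 (log2 -1.14, adjusted p = 0.0525) and mt-Nd6 (log2 -0.68, adjusted p = 0.0753) did not pass. The mean log2 level of the list was 12.68 ± 0.38 in WT and 11.99 ± 0.36 in OGTBKO libraries (SD, n = 4 each; exact two-sided permutation p = 0.0857). The share of reads in mitochondrial genes overlapped between the groups. It was 32.2% in WT 1, 30.2% in WT 2, 39.4% in WT 3 and 27.2% in WT 4, against 25.2% to 30.2% in OGTBKO libraries. With the library total as denominator the list was still called lower (median -0.57, camera adjusted p = 0.000236). WT 3, with the highest mitochondrial share, had the highest level, and the list was not called without it (median -0.43, adjusted p = 0.0922), without OGTBKO 2 (adjusted p = 0.0520), without OGTBKO 3 (adjusted p = 0.0675) or with the GC and length trend removed (adjusted p = 0.137). Nor was it called with quantile normalization, where its median was -0.21 (adjusted p = 0.253), with array weights (adjusted p = 0.0603) or with no filter (adjusted p = 0.0656). mt-Co3 shares nearly all its sequence with a nuclear copy on chromosome 1, so its own level is uncertain.

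**Figure D3:**
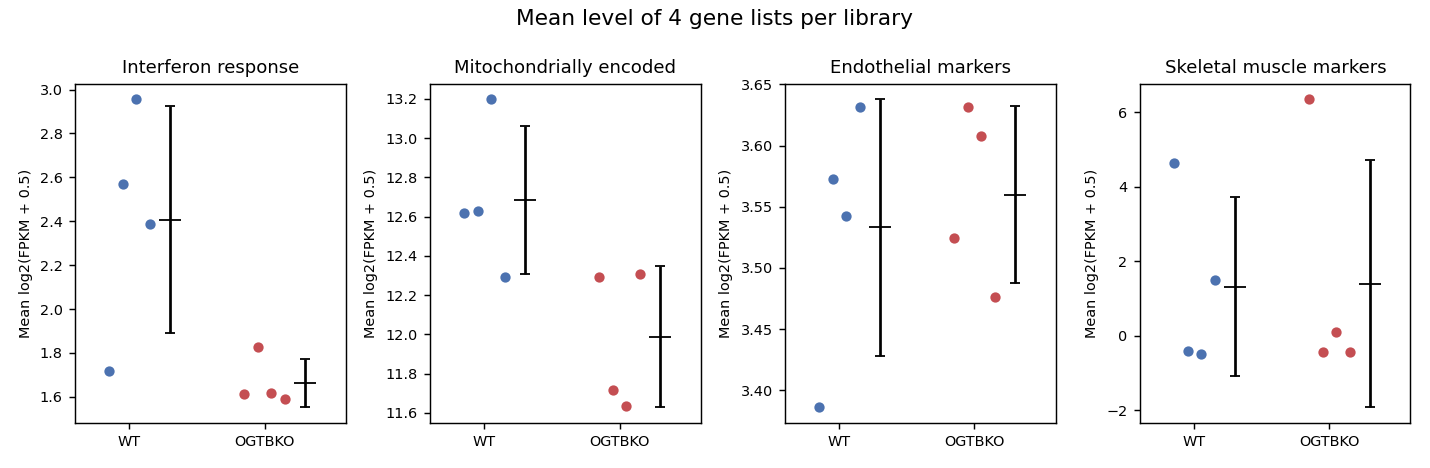
Mean log2(FPKM + 0.5) of the members of 4 gene lists in each library (points), with group mean and SD (bars, n = 4 each). Interferon response genes lay between 1.59 and 1.83 in OGTBKO libraries, and WT 1 (1.72) lay within that range; skeletal muscle markers stood at 4.65 in WT 1 and 6.35 in OGTBKO 1.

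Interferon-response genes were lower in OGTBKO tissue (camera adjusted p = 9.14e-05; median log2 -0.78; adjusted p = 0.936 with an estimated correlation). Of 18 measured, 3 were lower, 0 higher and 15 not past the test, and 10 were lower adjusted over the list alone. Ifi27, an interferon-induced mitochondrial protein and the most abundant of those that fell, went from 678 ± 58.5 to 380 ± 20.5 FPKM (log2 -0.83 ± 0.11, adjusted p = 0.00462). Oasl2, an oligoadenylate synthetase-like gene, fell from 2.01 ± 0.768 to 0.745 ± 0.362 FPKM (adjusted p = 0.0348) and the transcription factor Stat2 from 4.96 ± 1.78 to 2.72 ± 0.212 FPKM (adjusted p = 0.0497). The calls of Oasl2 and Stat2 each ended in 6 of the fits with a single library left out, and that of Ifi27 in none. Ifi44 did not pass (log2 -0.82, adjusted p = 0.0556). The mean log2 level of the list was 2.41 ± 0.52 in WT and 1.66 ± 0.11 in OGTBKO libraries (SD, n = 4 each; exact two-sided permutation p = 0.0571), with WT 1 inside the range of the OGTBKO libraries.

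Immune cell markers gave a mixed picture, and none of their lists was called. Of 24 macrophage markers 2 were higher and 1 lower (5 and 2 adjusted over the list alone). The integrin Itgax rose from 0.335 ± 0.0983 to 1.86 ± 0.541 FPKM (adjusted p = 0.00425) and the perforin-like Mpeg1 from 10.5 ± 2.54 to 21.4 ± 4.61 FPKM, while the haemoglobin scavenger receptor Cd163 fell from 6.38 ± 1.77 to 2.92 ± 1.41 FPKM (adjusted p = 0.0413, and 0.0592 with the GC and length trend removed). Trem2 did not pass (log2 1.10, adjusted p = 0.0519). Among 14 cytokines and chemokines 2 were lower and 0 higher (3 and 0 adjusted over the list alone), Ccl8 and Ccl12 (log2 -1.62, adjusted p = 0.0143). Lysosomal and lipid-handling genes had 1 of 20 higher, Atp6v0d2, and 1 lower, Lamp2 (log2 -0.72, adjusted p = 0.00952, and 0.0618 after the removal), with 4 and 2 adjusted over the list alone. Of 9 neutrophil and mast cell markers, S100a8 was lower (log2 -2.43, adjusted p = 0.0372) and the receptor Kit higher (log2 0.87, adjusted p = 0.0309); 1 and 2 were higher and lower adjusted over the list alone. Of 3 measured B cell markers 1 was higher: Ighm, the constant region of the immunoglobulin mu chain, from 11.3 ± 3.40 to 142 ± 78.3 FPKM (log2 3.49 ± 0.35, adjusted p = 0.00236). Igkc, the kappa light chain, was at 4.59 ± 5.06 and 12.2 ± 11.5 FPKM (adjusted p = 0.348). Of 2 measured T and NK cell markers 0 passed in limma (Ccl5, log2 0.58, adjusted p = 0.186; Nkg7, log2 0.26, adjusted p = 0.544), and 0 of 15 cell death genes were higher and 1 lower, Fas (log2 -0.52, adjusted p = 0.0209), also when adjusted over the list alone.

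Stress genes moved in part. Of 16 oxidative stress genes and NRF2 targets 4 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.105). The list was called higher with no filter on low values (adjusted p = 0.0104) and without both libraries numbered 1 (adjusted p = 0.0440). The glutathione transferases Gstm1 (from 46.2 ± 6.17 to 114 ± 16.2 FPKM, adjusted p = 0.00236) and Gstm2 (log2 1.23) rose, members of a family that can share reads, as did the superoxide dismutases Sod1 (log2 0.68) and Sod3 (log2 0.59). Of 18 integrated stress response genes 5 were higher and 1 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.130). Nupr1 (log2 0.93), Mthfd2 of mitochondrial one-carbon metabolism (log2 0.80), the serine synthesis enzyme Psat1 (log2 0.74) and Cebpb (log2 0.82; adjusted p = 0.0345, and 0.174 with the GC and length trend removed) rose. For these 2 lists the fry test of a shared direction gave adjusted p = 0.0497, and the mean level per library an exact permutation p = 0.0286, or 0.314 adjusted over the lists. With an estimated correlation both had an adjusted p = 0.936, and with the GC and length trend removed camera gave adjusted p = 0.137 for the NRF2 targets and 0.386 for the integrated stress response. Endoplasmic reticulum chaperones had 4 of 19 lower and 2 higher (6 and 2 adjusted over the list alone), with Hsp90b1 (log2 -0.54) and calnexin (Canx, log2 -0.59) lower and Dnajb11 (log2 0.54) and Syvn1 (log2 0.44; adjusted p = 0.0243, and 0.119 with the trend removed) higher. That list's median log2 change was -0.10, and 0.01 with the library total as denominator.

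In the tissue framework, extracellular matrix genes had 2 of 27 higher and 0 lower (1 and 0 adjusted over the list alone), Mmp12 and biglycan (Bgn, log2 0.67, adjusted p = 0.0408, and 0.0650 with the trend removed). Fibroblast and progenitor markers had 1 of 17 higher, the collagen Col5a3 (log2 1.22, adjusted p = 0.0110), and 1 lower, Ly6a (log2 -0.93, adjusted p = 0.0333), also when adjusted over the list alone. None of 15 cell cycle genes, 5 red blood cell markers and 14 skeletal muscle markers passed in limma, over all genes or adjusted over the list alone. Schwann cell and neuron markers had 1 of 8 lower, Cdh19 (log2 -0.58, adjusted p = 0.0272, and 0.154 with the trend removed; 2 lower adjusted over the list alone), and epithelial markers were not measured above the filter. Circadian clock genes had 2 of 14 lower (1 adjusted over the list alone), Clock (log2 -0.54, adjusted p = 0.00933, and 0.0711 with the trend removed) and Per1 (log2 -0.83, adjusted p = 0.0480). The call of Per1 ended in 7 of the fits with a single library left out. Immediate early genes, which respond to handling of tissue, had 1 of 10 higher (3 adjusted over the list alone), Junb (log2 1.09, adjusted p = 0.0178, and 0.0681 with the trend removed), and a median log2 change of 0.61 (camera adjusted p = 0.0693). That median was 0.94 without WT 4 and 0.40 without OGTBKO 2. Cytosolic ribosomal proteins had 5 of 26 higher and 1 lower (5 and 2 adjusted over the list alone), among them Rpl11 (log2 0.94), with pseudogene copies that can share reads. With the trend removed the balance turned, with 2 higher and 6 lower, and the median log2 change went from 0.08 to -0.04. Y-linked genes were present in all 8 libraries: Ddx3y measured 25.5 ± 3.37 and 21.6 ± 0.780 FPKM, and Uty was lower (log2 -0.47, adjusted p = 0.0162), a call lost with the trend removed (adjusted p = 0.545).

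**Figure D4:**
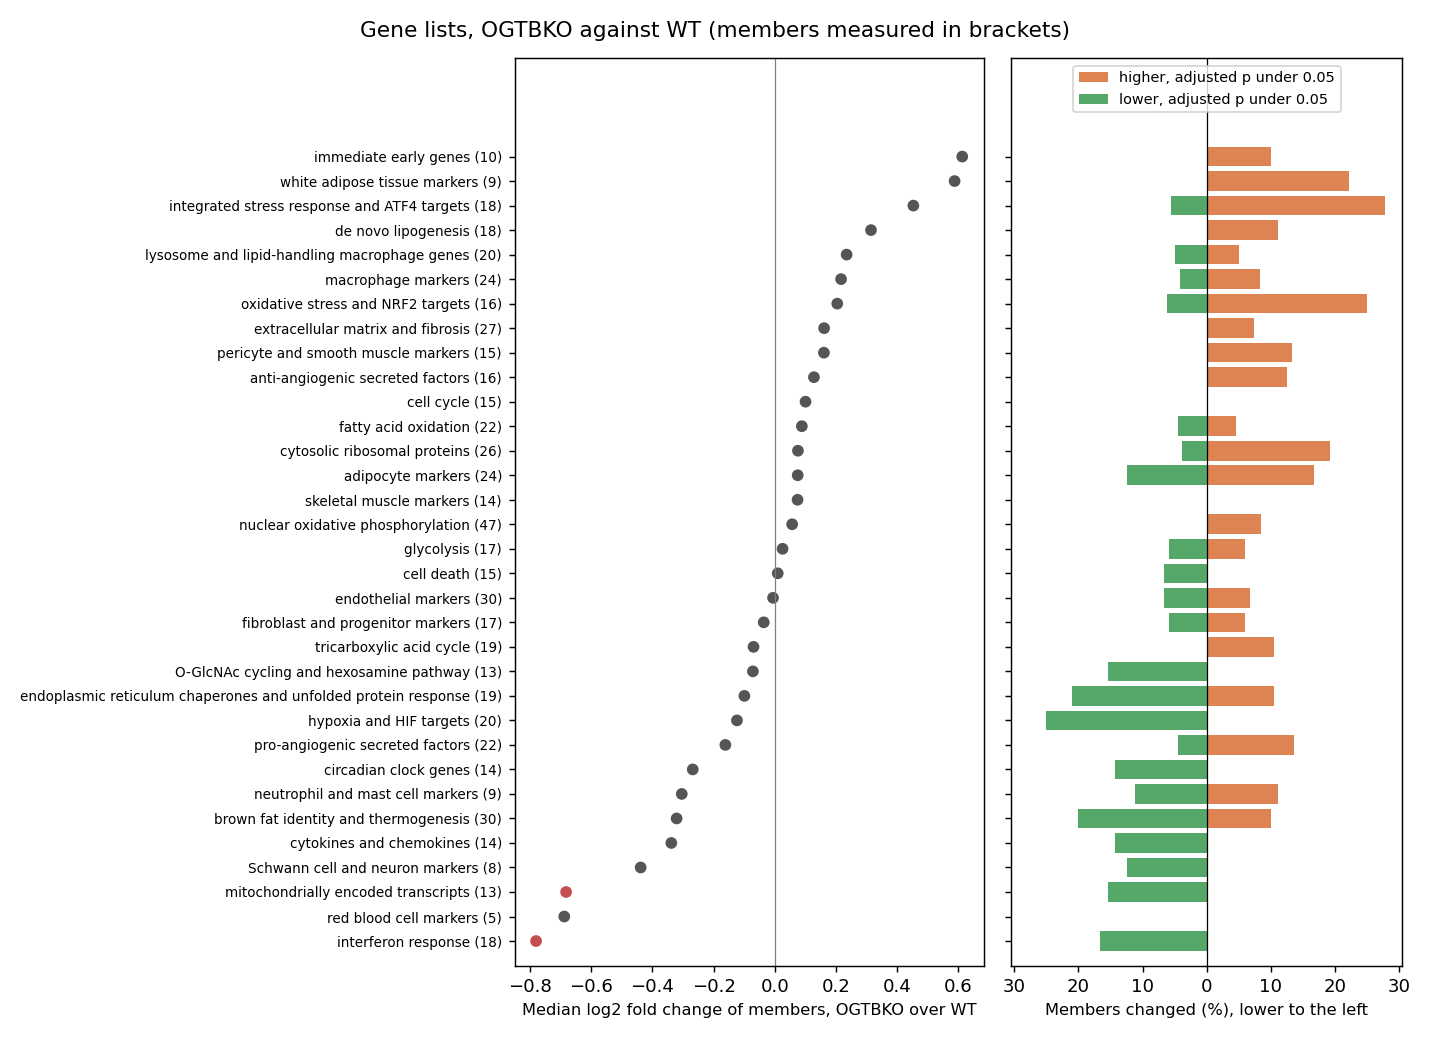
Median log2 fold change, OGTBKO over WT, of the measured members of 33 gene lists (left; red, camera adjusted p under 0.05) and the percentage of members higher (orange) or lower (green) at adjusted p under 0.05 (right). Interferon response (median -0.78) and mitochondrially encoded transcripts (median -0.68) were the 2 lists called.

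In all, 2 of 33 lists were called by camera with its preset correlation, both lower, and 0 with an estimated correlation, where 0 lists had an unadjusted p under 0.05. The libraries separated by genotype on the first principal component (33.6% of the variance). On the second (21.0%), WT 1 and OGTBKO 1 stood apart from the other 6 libraries, and they also had the highest levels of skeletal muscle markers, with mean log2 levels of 4.65 and 6.35 against -0.48 to 1.51 elsewhere. Without these 2 libraries, a setting chosen after the data were seen, 1925 genes were called, of which 1374 were among the 2050, and 7 lists, among them macrophage markers, cell cycle, immediate early genes and NRF2 targets as higher. Leaving out a single library called immediate early genes (without WT 4, OGTBKO 1 or OGTBKO 4), macrophage markers and cell cycle (without OGTBKO 1), and white adipose tissue and matrix genes (without OGTBKO 4), all higher. It also called lipogenesis higher and neutrophil markers lower (without WT 3), and red blood cell markers lower (without WT 2). Correlations of log2 values were 0.934 to 0.974 within WT, 0.948 to 0.976 within OGTBKO and 0.925 to 0.950 between the groups (across genes, which are not independent replicates).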

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

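The 7 tests of GC content and length, of mitochondrial transcripts and of Ighm were chosen only after the result was seen, whereas the comparison with other splits of the samples was planned beforehand.

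The 8 libraries were split 4 against 4 in all 35 ways. The real split gave 2050 genes changed, 1068 higher, 982 lower and 333 changed at least 2-fold. It was the 1 split of 35 that gave as many of each, the smallest share that this comparison allows. The highest of the others gave 3, 2, 2 and 3. The others mix the genotypes, so a group difference adds to their spread and lowers their calls. The comparison cannot tell genotype from the GC trend, which separates the same groups. For the gene lists chance was not excluded, since 34 of the 35 splits called at least 2 lists and the highest of the others called 15.

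The changed genes followed GC content and gene length, with a slope of 0.0230 log2 per percentage point of GC between the groups. The trend as modelled, smooth on GC content and length, did not account for all of the calls. After its removal 1051 of the 2050 genes were still called with the same sign, their median absolute log2 change going from 0.73 to 0.69. Effects of library preparation outside that trend would remain and were not tested. For the 999 calls that ended the median went from 0.53 to 0.34, and there a trend of library preparation cannot be told apart from an effect of genotype, as the GC slopes separated the groups completely (exact permutation p = 0.0286, the smallest possible). The knockout itself, through genes that differ in GC content, may give such a slope, and this was not tested.

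Mitochondrially encoded transcripts were lower as a list, and 3 technical explanations stayed open, the first examined for some members only. Reads divided between a gene and a near-identical copy on chromosome 1 can bear only on members with such a copy. For 5 of these, gene and copy summed had a median log2 change of -0.75 (-1.10 to -0.54), against -1.12 for the genes alone. All of these sums were still lower, but they did not separate the groups (exact permutation p = 0.0857). How much of the fall of these members a division of reads accounts for could therefore not be told. The 6 members without a match among the annotated copies compared had a median of -0.47 (-1.35 to -0.09). Other copies were not searched for. These members include mt-Atp8, which lies between mt-Co2 and mt-Atp6, both with a copy. A division of reads was therefore not excluded for mt-Atp8. The WT 3 library alone left a difference of -0.52 in the mean log2 level when it was removed (exact permutation p = 0.171). The median of -0.68 went to -0.46 with the GC and length trend removed (adjusted p = 0.137), to -0.31 with GC alone (adjusted p = 0.310), to -0.81 with length alone (adjusted p = 0.00639), and to -0.24 with both removed and WT 3 left out (adjusted p = 0.550). A lower level of mitochondrial transcripts in the knockout stays possible and was not tested apart from these.

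Ighm was higher in 4 of 4 OGTBKO libraries than in any WT library, 13.0 times by summed reads, while the 9 other B cell markers with at least 10 reads had a median ratio of 1.48 (0.913 to 2.52). B cells or plasma cells in the OGTBKO tissue cannot be told apart from another origin, because the other markers varied widely between libraries: their summed level had a log2 difference of 1.14 with a 95% interval of -1.31 to 3.59, which reaches past 0.5 of the ratio of Ighm (log2 2.71). Without the kappa chain Igkc (0 to 11.8 FPKM in WT and 1.99 to 26.7 FPKM in OGTBKO libraries) the interval was -0.85 to 1.75, from markers near the floor. The GC and length trend could not account for the change, with a log2 change of 3.30 after its removal. An effect of the genotype, or a strain variant near the locus, may be another hypothesis, and neither was tested.

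Some libraries stood far from the other 3 of their group, in 19 of 304 groups of 4 examined; chance gives about 1 in 20 groups, or 15.2. Among OGTBKO libraries these were, in FPKM, Cox5b (69.8) and Nkg7 (1.29) in OGTBKO 2, Nr4a3 (1.36), Nupr1 (4.11) and Uty (3.80) in OGTBKO 4, and S1pr1 in OGTBKO 1 (18.1). Among WT libraries they were Fas (12.1) and Vash1 (0.872) in WT 3, Nnat in WT 1 (13.0), Wwc1 in WT 2 (0.0282), and Idh2 (80.0), Kit (1.15), Mmp12 (0.693), Nt5dc2 (1.34) and Sdc4 (64.5) in WT 4. By mean log2 level of a list they were interferon response in OGTBKO 2 (1.83), O-GlcNAc cycling in WT 3 (1.98), skeletal muscle markers in OGTBKO 1 (6.35) and white adipose tissue markers in OGTBKO 4 (2.61).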

How the results depend on the processing

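The removal of GC and length trends, the library total as denominator, the omission of both libraries numbered 1 and the omission of WT 3 with the trends removed were chosen after the data were seen; all other alternatives were planned. Ogt was lower and called in all of them (log2 -0.83 to -1.10), and of the 2050 genes 1 had the opposite sign, without a call, after the GC and length trends were removed. Against 2050 genes changed (1068 higher, 982 lower), 1229 were called with no filter (492 lower), which tests more genes, 3516 with array weights (1757 higher, 1759 lower), 1359 with the GC trend removed (608 lower), and 1229 with the library total as denominator (249 lower). With the GC and length trends removed 643 were lower, and limma voom gave 523 genes changed at least 2-fold against 333. Leaving out 1 library, which lowers the number of samples, gave 692 to 2122 genes changed, 416 to 1125 higher, 276 to 1004 lower, 207 to 394 changed at least 2-fold and 1 to 5 lists. Against 2 lists called, 1 was called with quantile normalization, with mitochondrial genes removed, with array weights, with the GC trend removed and with the GC and length trends removed, 7 without both libraries numbered 1, 5 without WT 3 and the trends, and 0 with an estimated correlation, where 0 lists had an unadjusted p under 0.05 and fry called 2 by its directional test and 23 by its mixed test, which asks for change in either direction. With no filter 3 lists were called, NRF2 targets and white adipose tissue markers higher and interferon response lower. Apart from fewer genes or samples, the cause was not tested. Of 96 called genes named, other than Ogt, 34 kept the call throughout; the trend removal ended 27 and leaving out at least 1 library 52, with 0 changes of sign. With the replicate number as a block, 888 genes were called (561 higher, 327 lower) and 3 lists, immediate early genes (adjusted p = 0.0429) in addition, and 26 of the genes named were not. Deviations of same-numbered samples correlated at 0.22, 0.17, 0.01 and -0.01. Libraries numbered 1 and 2 correlated best with their own number, those numbered 3 and 4 did not. A pairing of the samples by number was therefore neither shown nor excluded. At this depth and spread 15.4% of simulated 1.5-fold changes were recovered. The simulation held far fewer changed genes than the 2050 called here, which makes the adjustment stricter, so that share may be too low for the real data.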

Other observations

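The 3 groups of genes described here were put together, and their tests chosen, only after the values were seen, so they are descriptions and their p-values are not independent evidence. Genes of MHC class II antigen presentation were higher in OGTBKO tissue: 6 of 10 measured rose and 0 fell (median log2 0.96; camera adjusted p = 6.08e-06 over the 3 groups; adjusted p = 0.113 with an estimated correlation). They included the invariant chain Cd74 (log2 1.36), H2-Ab1 (log2 0.92) and H2-Eb1 (log2 1.23), which form or accompany the peptide-presenting dimer, and H2-DMa (log2 1.37) and H2-DMb1 (log2 1.32), which load it. The mean level per library gave an exact permutation p of 0.0286, the smallest possible. Markers of antigen-presenting cells moved with them in part: Itgax rose from 0.335 ± 0.0983 to 1.86 ± 0.541 FPKM and Mpeg1 from 10.5 ± 2.54 to 21.4 ± 4.61 FPKM (n = 4 each), while Cd163 fell from 6.38 ± 1.77 to 2.92 ± 1.41 FPKM (adjusted p = 0.0413). The macrophage list, with 2 of 24 markers higher, 1 lower and 21 not past the test, at a mean log2 level of 2.96 in WT and 3.29 in OGTBKO tissue, was not called (adjusted p = 0.194), but was without OGTBKO 1 (adjusted p = 0.00367) and without both libraries numbered 1 (adjusted p = 0.00298).

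Targets of FoxO transcription factors and of fasting were lower, 9 of 22 measured and 0 higher (median log2 -0.52; camera adjusted p = 1.30e-05 over the 3 groups; adjusted p = 0.113 with an estimated correlation), with an exact permutation p of 0.0286. Foxo1 itself fell by 1.15 on the log2 scale (adjusted p = 0.00391), Klhl24 by 1.08, the pyruvate dehydrogenase kinase Pdk4 by 0.82, the insulin receptor Insr by 0.57 and the autophagy gene Gabarapl1 by 0.81. Of 18 cytosolic heat shock proteins 4 were lower and 0 higher (median log2 -0.29; camera adjusted p = 0.00534; adjusted p = 0.156 with an estimated correlation), among them Hsph1, the constitutive chaperone Hspa8 (log2 -0.58) and Hsp90ab1 (log2 -0.39); the exact permutation p was 0.0857.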
